A study of Homo sapiens with 8 samples.

How the data were processed

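Total RNA from HEK293 cells treated with 25 nM LMI070 or with DMSO was depleted of ribosomal RNA and sequenced, per the labels, as 8 stranded libraries on an Illumina sequencer in lanes 7 and 8. Per the submitters' processing notes the reads were aligned to GRCh38 with STAR 2.6.0c. The deposited tables are that aligner's splice junction tables, and per the file headers their values are raw counts of uniquely mapped and of multiply mapped reads that cross each junction, 1 table per library and without normalization by the authors. Alignment parameters, read filters and the annotation release used in the alignment are not stated, and the tables hold no reads within exons or introns. Values are uniquely mapped counts unless stated otherwise. Nothing in the labels says whether libraries of a group came from separate cultures, so every p measures the spread between these libraries. Replicates in a group differed by more than counting error, so none repeats the counts of another. The chi-square per degree of freedom of pairs within lanes 8 and 7 was 1.94 and 6.90 in DMSO and 1.89 and 3.70 in LMI070. For pairs across lanes it was 3.85 to 7.65 in DMSO and 10.5 to 12.8 in LMI070. These values do not tell separate cultures from separate preparations of the same RNA.

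Junctions were matched to the introns of GENCODE 29; 242867 of the 654181 junctions were annotated, and the annotation mark in the deposited tables gave the same answer for 99.8%. A genome sequence was not used here, since only transcript sequences were available. A cassette exon was defined by 2 inclusion junctions and the junction that skips it, on one strand, with a length of 3 to 500 nt; exons that share a 5′ splice site were counted once. Inclusion was the mean of both inclusion junctions divided by that mean plus the skipping reads. Exons needed at least 10 inclusion reads and 10 skipping reads over all libraries and at least 10 reads in each library, which left 33576. Paired inclusion and skipping counts were fitted with the quasi-likelihood F test of edgeR 4.0.16 under R 4.3.3, with a coefficient for each library, inclusion by lane and inclusion by treatment. Benjamini-Hochberg adjustment covered all exons. An exon was called at an adjusted p under 0.05 and a change of at least 10 percentage points, and it was unannotated when neither inclusion junction was in GENCODE. Junction usage was tested in the same way against all junctions that share a splice site, with at least 20 reads over all libraries and 10 reads for the sites in each library. Where a group had a count of 0, a floor of 3 counts over the group was used, divided between both inclusion junctions of an exon, for counting error only.

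Spliced reads per gene were the sum over its annotated junctions; 21608 genes had such a junction, and 95.9% of annotated reads lay in introns of a single gene. The edgeR filter for expression kept 13487 genes. They were scaled with TMM factors and tested with lane and treatment in the model. Levels are given as CPM, counts scaled by library total and TMM factor. The standard error of a log2 fold change was derived from the F statistic. An interaction of treatment with lane was fitted in addition. Gene lists were tested with camera of limma 3.58.1 at a correlation of 0.01, for lists with at least 3 measured genes. Each was also tested with a correlation estimated from the data and with fry. The fry test asks whether a list moves at all, without comparison with other genes. The counts adjusted over the list alone apply the correction to the members of that list only. The 24 lists were written before the data were examined. They were the SMN complex; targets known from other work on LMI070 or risdiplam; targets named by the study on these samples; SF3a, SF3b and U2 snRNP proteins; U1 snRNP and Sm proteins; SR proteins and poison-exon regulators; nonsense-mediated decay factors; and noncoding host genes sensitive to that decay. Further lists covered p53 targets, integrated stress and unfolded protein responses, heat shock proteins, cholesterol synthesis, G2 and M phase, DNA replication and S phase, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, autophagy and interferon response. The remaining lists held HEK293 identity genes and markers of fibroblasts, blood, keratinising or cervical epithelium and hepatocytes. Shares of reads per library were compared with an exact permutation test, two-sided, over all 70 assignments. These assignments do not keep the lanes balanced, and no permutation within lanes was run. Sequence ends were compared with Fisher's exact test, two-sided.

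Genes in the text were named by a fixed rule. It took the 20 called unannotated exons with the largest change, the 8 called annotated exons with the largest rise and the 8 with the largest fall, and 5 junctions each way outside those exons. It also took up to 12 genes each way past the gene test with a mean of at least 100 reads, all with the same direction in both lanes, and up to 4 members of each list. Levels of SMN1, SMN2, HTT, SF3B3, BECN1, C12orf4, PDXDC2P, FOXM1, STRN3, SLC25A17, GGCT, MADD, APLP2, POMT2, VPS29 and PDXDC1 were given whatever their result, where measured. For each of these genes the exon with the smallest p was given, among 2 to 11 exons tested per gene. Other genes are marked as named after their values were seen.

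The tests were tested on simulated data drawn from the real totals. For exons and junctions the spread between libraries was a fixed setting, not estimated from the data. The simulated data held no lane effect and no library that stands apart, and no changed exon started at 0% inclusion. Genes of the simulated lists were drawn independently of each other. The false calls below therefore hold for these settings and may be too few for the real libraries. For exons that started between 1% and 60% inclusion, 59 of 100 changes of 15 points and 82 of 100 changes of 30 points were recovered, with 0 false calls. For junction usage, 40 and 77 of 100 were recovered, with 0 false calls. For genes, 38 of 67 fold changes of 1.3 (56.7%), 56 of 67 of 1.5 (83.6%) and 63 of 66 of 2 (95.5%) were recovered, with 11 false calls. For lists moved by a fold of 1.15, 10 of 10 were recovered, with 0 false calls.

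Alternatives were DESeq2 1.42.0 and its size factors, diffSpliceDGE of edgeR on clusters made with igraph 2.1.4, no filter on low counts or at least 50 reads per library, no lane term, other minimum changes, multiply mapped reads added, and each library left out in turn. Chosen after the data were seen were exons with balanced junctions, exact GENCODE exons, each lane alone, both libraries that stand apart left out, the sequence test on annotated exons, junctions outside the host intron, and SMN exon 7 with multiply mapped skipping reads. Other splits of the libraries into 4 and 4 were refitted, all 35 of them, or 21 for junction usage. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the main results.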

Results

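HEK293 is an established human embryonic kidney cell line. The cells had been treated with LMI070 (branaplam), a small molecule that alters pre-mRNA splicing, at 25 nM, or with dimethyl sulfoxide (DMSO), the solvent used as control. Total RNA depleted of ribosomal RNA was sequenced. The deposited tables give, for each library, the number of reads that cross each splice junction. Each group had 4 libraries, replicates 9 to 12 for DMSO and 13 to 16 for LMI070. Lanes 7 and 8 of the sequencer each held 2 libraries of each group, and the labels' run codes differ between the lanes. Uniquely mapped junction reads numbered 21975349, 26716014, 25324148 and 22079776 in DMSO replicates 9, 10, 11 and 12. They numbered 36131054, 25751365, 20369466 and 21464363 in LMI070 replicates 13, 14, 15 and 16. Over the 8 libraries 654181 junctions had at least 1 uniquely or multiply mapped read, and 242867 of them were introns of the GENCODE 29 annotation. DMSO replicate 12 and LMI070 replicate 16 lay apart from the other libraries in a multidimensional scaling of spliced reads per gene. All positions are on GRCh38.

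The first comparison asked which exons absent from the annotation are included when LMI070 is present, as the study's title concerns splicing under the control of a drug. The largest rise was in ZNF37BP, a zinc finger pseudogene transcript. Its 63-nt exon on chromosome 10 (42551400 to 42551462) went from 11.1% ± 1.86 to 51.4% ± 5.54 inclusion (SD, n = 4 per group). In C12orf4, a 135-nt exon in the first intron (chromosome 12, 4537380 to 4537514) had no read in DMSO, where 171 reads skipped it, and reached 35.9% ± 3.21 in LMI070. The pseudogene PDXDC2P gained a 63-nt exon (chromosome 16, 70031186 to 70031248) that was at 0% in DMSO and at 32.4% ± 6.84 in LMI070. DYRK1A, a protein kinase gene, rose from 1% ± 2 to 33.2% ± 8.44 for a 71-nt exon between exons of its untranslated region (chromosome 21, 37422582 to 37422652), measured on 24 and 25 reads of its junctions in LMI070.

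Genes with smaller rises came from many processes. GTF2H2, which encodes a subunit of the transcription and repair factor TFIIH, rose from 51.3% ± 5.98 to 75.8% ± 3.50 for a 53-nt exon (chromosome 5, 71038429 to 71038481). The long noncoding RNA LINC02210 rose from 2.53% ± 0.832 to 26.6% ± 2.16 for a 361-nt exon (chromosome 17, 45630246 to 45630606). TENT2, a poly(A) polymerase gene, rose from 7.52% ± 2.92 to 29.4% ± 8.53 (chromosome 5, 79641455 to 79641517). FHOD3, a formin gene, rose from 0.565% ± 0.752 to 20.8% ± 5.29 (chromosome 18, 36742377 to 36742468). TET1, a gene for a DNA demethylation enzyme, went from 0.610% ± 1.22 to 17.3% ± 13.1 (chromosome 10, 68680872 to 68680967), with the LMI070 libraries spread from 4.76% to 35.5%. TIAM1, a gene for a Rac exchange factor, went from 9.63% ± 1.83 to 23% ± 1.01 (chromosome 21, 31268411 to 31268695). FAM3A reached 17.6% ± 4.35 from 0.758% ± 1.52 (chromosome X, 154512568 to 154512706), and the SUMO protease gene SENP6 reached 13.2% ± 3.14 from 1.98% ± 1.32 (chromosome 6, 75621927 to 75621971). SKP1, a subunit gene of SCF ubiquitin ligases, held 2 exons (chromosome 5, 134175290 and 134175337 to 134175385). They were at 23.2% ± 5.26 and 22.5% ± 5.01 in LMI070, both with 0 reads in DMSO. Both share 61 reads of the upstream junction in LMI070, with 5 and 2 reads at their own downstream junctions. The skipping junction they are set against had 83 reads in DMSO and 110 in LMI070. Other SKP1 exons with the same 3′ splice site rose by 0.599 and 0.780 points, so these values are not a share of all SKP1 RNA. WDR27 held exons ending at 169661750 on chromosome 6 that started at 169661703 (20.8% ± 2.05) and 169661663 (11.8% ± 2.57), also with 0 reads in DMSO. These share 29 upstream reads in LMI070, with 34 and 3 reads downstream. GXYLT1, a xylosyltransferase gene, held exons on chromosome 12 from 42095151 (15.5% ± 3.34) and 42095102 (11.6% ± 3.21) to 42095214, again with 0 reads in DMSO. Its forms share 95 upstream reads in LMI070, with 43 and 1 reads downstream. CACNA2D1, a calcium channel subunit gene, held exons on chromosome 7 from 82076016 and 82076028 to 82076122. Their values rose from 0.152% ± 0.303 to 12.2% ± 4.73 and 12.1% ± 5.28. Both rest on the same 74 upstream reads in LMI070, with 2 and 1 reads downstream, so they measure the shared junction rather than either form.

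For each of these 20 exons all 4 LMI070 libraries lay above all 4 DMSO libraries, as their choice by the size of the change favours. With edgeR, 23 unannotated exons in 17 genes were called higher among 7040 tested, at an adjusted p under 0.05 and a change of at least 10 percentage points. The other 3 called exons, named after their values were seen, were a further form each in TET1 and WDR27 and an exon of EVC at 10.7% ± 2.47. No exon was called lower by edgeR or DESeq2, while at an unadjusted p under 0.05 edgeR had 192 lower, 2 of them by at least 10 points. Without the minimum change, 92 exons in 68 genes were higher and 3 lower (2 in RPL26 and 1 in USP25), and 48 of the 92 had 0 inclusion reads in DMSO. A count of 0 in DMSO allows inclusion of up to 0.870% in C12orf4, 0.744% in PDXDC2P, 1.78% in SKP1, 0.997% in WDR27 and 0.407% in GXYLT1, for counting error only. In 14 of the 23 the less covered junction had at least 20% of the reads of the other. The FAM3A, SKP1, CACNA2D1 and longer GXYLT1, WDR27 and TET1 forms did not, so their 5′ splice sites are poorly resolved. Forms of a gene that share a junction are counted separately among the 23, though they rest in part on the same reads. Within lanes the number called was 12 in lane 7 and 24 in lane 8. TET1 did not pass with DESeq2 (adjusted p 0.0686), without the low-count filter (0.124), in lane 7 alone (0.477) or without DMSO replicate 10 (0.0503), and without LMI070 replicate 14 its change was 10.6 points (0.0527). TIAM1 did not pass with DESeq2 (0.294), without the filter (0.522), in lane 7 or lane 8 alone (0.592 and 0.0940), without DMSO replicate 9 (0.122) or without LMI070 replicate 15 (0.0531). FAM3A did not pass without the filter (0.278). In lane 7 alone FAM3A (0.410), TENT2 (0.192), both SKP1 forms (0.0506 and 0.0608) and the 88-nt WDR27 form (0.0799) did not pass.

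**Figure D1:**
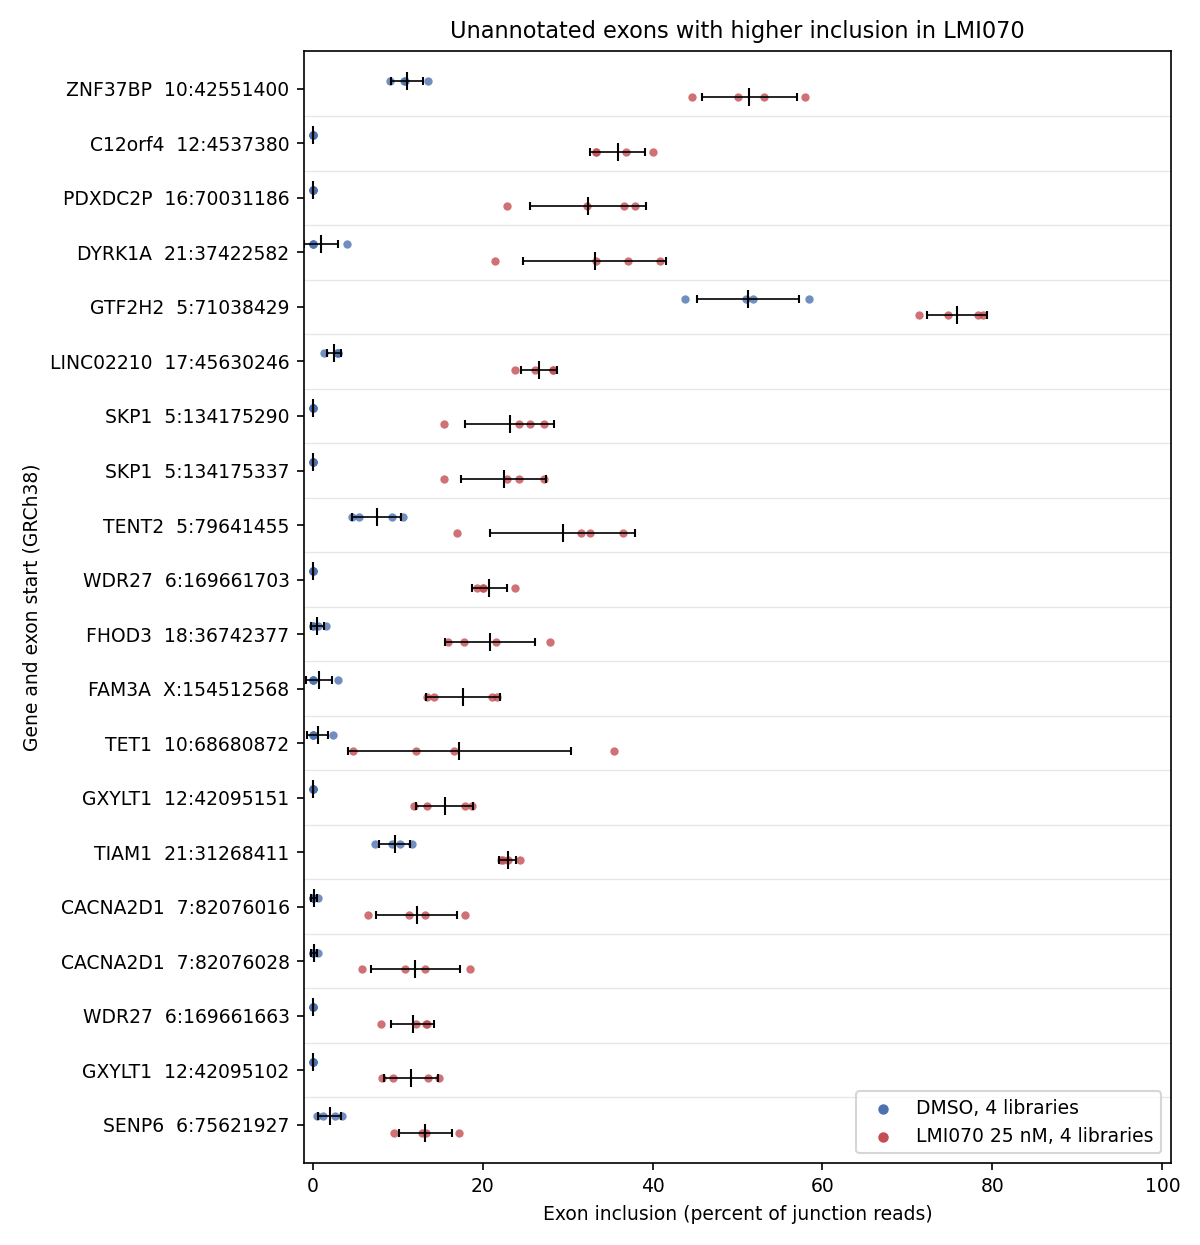
Inclusion of the 20 unannotated exons with the largest change, in percent of junction reads (horizontal axis), 1 line per exon named by gene and exon start on GRCh38. Points are libraries, 4 of DMSO in blue and 4 of LMI070 in red, and black ticks with bars are means with SD. The LMI070 libraries lie to the right of the DMSO libraries in every line, and the C12orf4 exon goes from 0% to 35.9%.

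The same test on annotated cassette exons asked which known alternative exons respond. POMT2, which encodes a protein O-mannosyltransferase, changed most: its 39-nt exon (chromosome 14, 77287233 to 77287271) rose from 4.79% ± 1.95 to 49.3% ± 3.04 (SD, n = 4). STRN3, a striatin gene, rose from 43.8% ± 1.32 to 76.6% ± 5.20 for a 111-nt exon (chromosome 14, 30929201 to 30929311). VPS29, a retromer subunit gene, rose for a 12-nt exon from 53.4% ± 5.34 to 79.8% ± 3.13 (chromosome 12, 110499535 to 110499546). Its 90-nt form, from 110499457 to the same end, rose from 40.2% ± 3.95 to 70.5% ± 3.79, but its downstream junction had 11% of the reads of the shared upstream junction. PDE7A, a cAMP phosphodiesterase gene, rose from 8.40% ± 4.63 to 35.5% ± 5.54 (chromosome 8, 65780844 to 65780947). KDM6A, a histone demethylase gene, rose from 6.04% ± 1.3 to 32.8% ± 3.85 (chromosome X, 45106542 to 45106649). TRIM65, a ubiquitin ligase gene, rose from 71.1% ± 4.52 to 94.9% ± 1.10 (chromosome 17, 75891813 to 75891878). LIMCH1, an actomyosin regulator gene, rose from 70.4% ± 5.25 to 91.8% ± 6.07 (chromosome 4, 41638932 to 41638967). RAB3IP, a gene for a Rab exchange factor, was the 1 annotated exon called lower and went from 95.4% ± 3.43 to 84.5% ± 3.95 (chromosome 12, 69812778 to 69812877).

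Over 18783 annotated exons tested, edgeR called 15 higher in 13 genes and 1 lower. The remaining genes called higher, named after their values were seen, were TAF2, LARP7, FAAP20, GGCT, ASAP1 and SLC7A6. LARP7, which encodes a protein of the 7SK particle, rose from 1.70% ± 0.440 to 21.9% ± 1.94, and a 9-nt exon of ASAP1 rose from 0.236% ± 0.472 to 13.2% ± 4.20. Exons with only 1 annotated junction gave 6 higher calls in TRIM65, KDM6A, LARP7 and MYCBP2 among 7753 tested; in MYCBP2 inclusion rose from 34.4% ± 4.27 to 59.0% ± 3.42. Of these 6, MYCBP2 alone had balanced junctions, so the others rest on a junction shared with another form. DESeq2 called 9 annotated exons higher and 0 lower; LIMCH1 (adjusted p 0.366), GGCT (0.244) and RAB3IP (0.490) did not pass with it. LIMCH1 and RAB3IP also passed in neither lane alone (adjusted p 0.0785 and 0.826 in lanes 7 and 8 for LIMCH1, 0.285 and 0.177 for RAB3IP), and neither passed without the low-count filter (0.308 and 0.164). LIMCH1 did not pass without DMSO replicate 12 (0.0760) or LMI070 replicates 13 (0.0731), 14 (0.0657) or 16 (0.0676), nor RAB3IP without DMSO replicate 11 (0.129).

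Genes known from other work on LMI070 and related drugs, and genes that the study itself named on these samples, were looked up by rule. The latter are not independent evidence. Each exon given had the smallest p of those tested in its gene, from 2 in SMN1 to 11 in FOXM1. That choice favours exons that changed. HTT, the huntingtin gene, included a 115-nt exon in intron 49 (chromosome 4, 3213622 to 3213736) at 0.210% ± 0.420 in DMSO and 7.70% ± 1.54 in LMI070 (SD, n = 4, edgeR adjusted p 5.92e-05, higher in 4 of 4 libraries). Its upstream junction had 28 reads in LMI070 and 0 in DMSO, and its downstream junction 4 and 1. SF3B3, which encodes a subunit of the SF3b splicing complex, included a 54-nt exon in intron 2 (chromosome 16, 70527376 to 70527429) at 4.14% ± 0.739 in LMI070. No read joined it in DMSO, where 2900 reads skipped it, which allows up to 0.0517%. BECN1, an autophagy regulator gene, included a 39-nt exon (chromosome 17, 42811292 to 42811330) at 9.91% ± 2.15 in LMI070 and had 0 reads in DMSO, which allows up to 0.225%. PDXDC1 rose from 0.253% ± 0.253 to 5.94% ± 1.23 (chromosome 16, 15009499 to 15009561). Among annotated exons, GGCT rose from 69.0% ± 2.44 to 83.7% ± 2.32 (chromosome 7, 30500536 to 30500681), and APLP2 from 27.9% ± 1.59 to 34.9% ± 1.33 (chromosome 11, 130123612 to 130123779). FOXM1, a cell cycle transcription factor gene, rose from 5.13% ± 1.28 to 12.3% ± 1.41 (chromosome 12, 2861299 to 2861412). MADD rose from 1.76% ± 1.80 to 11.1% ± 4.66 (chromosome 11, 47292543 to 47292596) and SLC25A17 from 0.930% ± 0.520 to 5.24% ± 2.41 (chromosome 22, 40797284 to 40797336). These edgeR adjusted p values passed, but the changes in HTT, SF3B3, BECN1, PDXDC1, FOXM1, APLP2, MADD and SLC25A17 were under 10 points. APLP2 (1.00), FOXM1 (0.359), SLC25A17 (0.306) and MADD (0.165) did not pass with DESeq2, and the last 3 did not pass without the low-count filter (0.156, 0.208 and 0.185). In lane 7 alone HTT (0.145), APLP2 (0.548), FOXM1 (0.194), SLC25A17 (0.637) and MADD (0.0606) did not pass, nor did FOXM1 (0.112) and MADD (0.847) in lane 8 alone. MADD did not pass without DMSO replicate 11 (0.114) or LMI070 replicate 13 (0.164), nor SLC25A17 without DMSO replicate 10 (0.0700) or LMI070 replicate 14 (0.155). Exon 7 of SMN2 was at 98.9% ± 0.801 in DMSO and 99.3% ± 0.557 in LMI070 from uniquely mapped reads, of which 6 and 5 skipped it. Skipping reads of SMN1 and SMN2 map to both genes, so unique reads do not measure its skipping. The SMN1 exon with the smallest p (chromosome 5, 70946707 to 70946815) was at 0.193% ± 0.159 in DMSO and 0.428% ± 0.443 in LMI070. It did not pass.

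**Figure D2:**
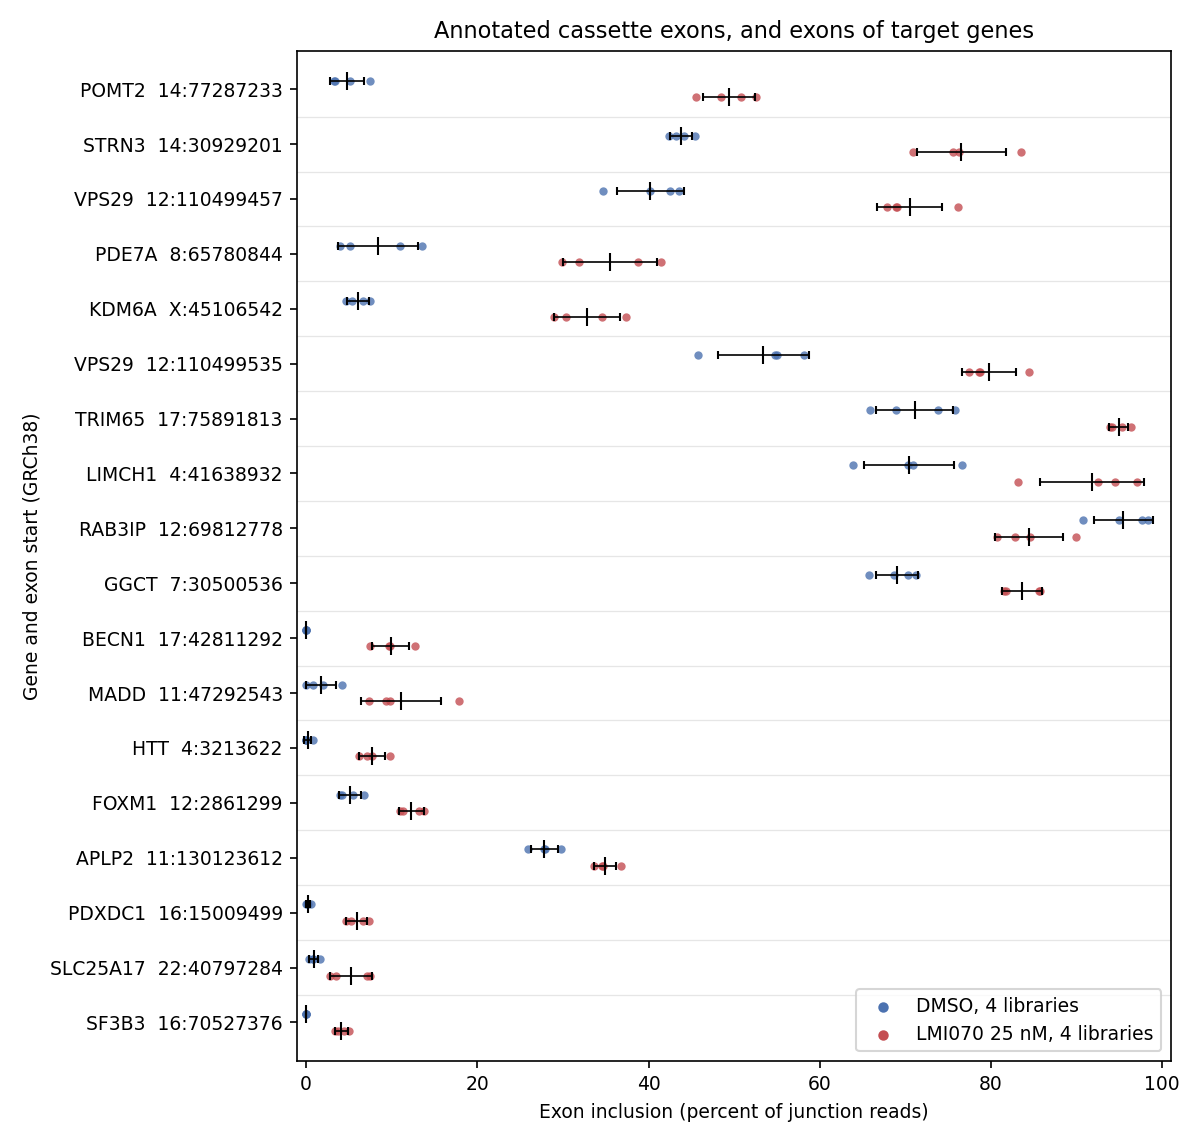
Inclusion of the annotated exons named in the text and of exons in genes known as targets, in percent of junction reads (horizontal axis), 1 line per exon named by gene and exon start on GRCh38. Points are libraries, 4 of DMSO in blue and 4 of LMI070 in red, and black ticks with bars are means with SD. RAB3IP is the line in which LMI070 lies to the left, at 84.5% against 95.4%.

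**Figure D3:**
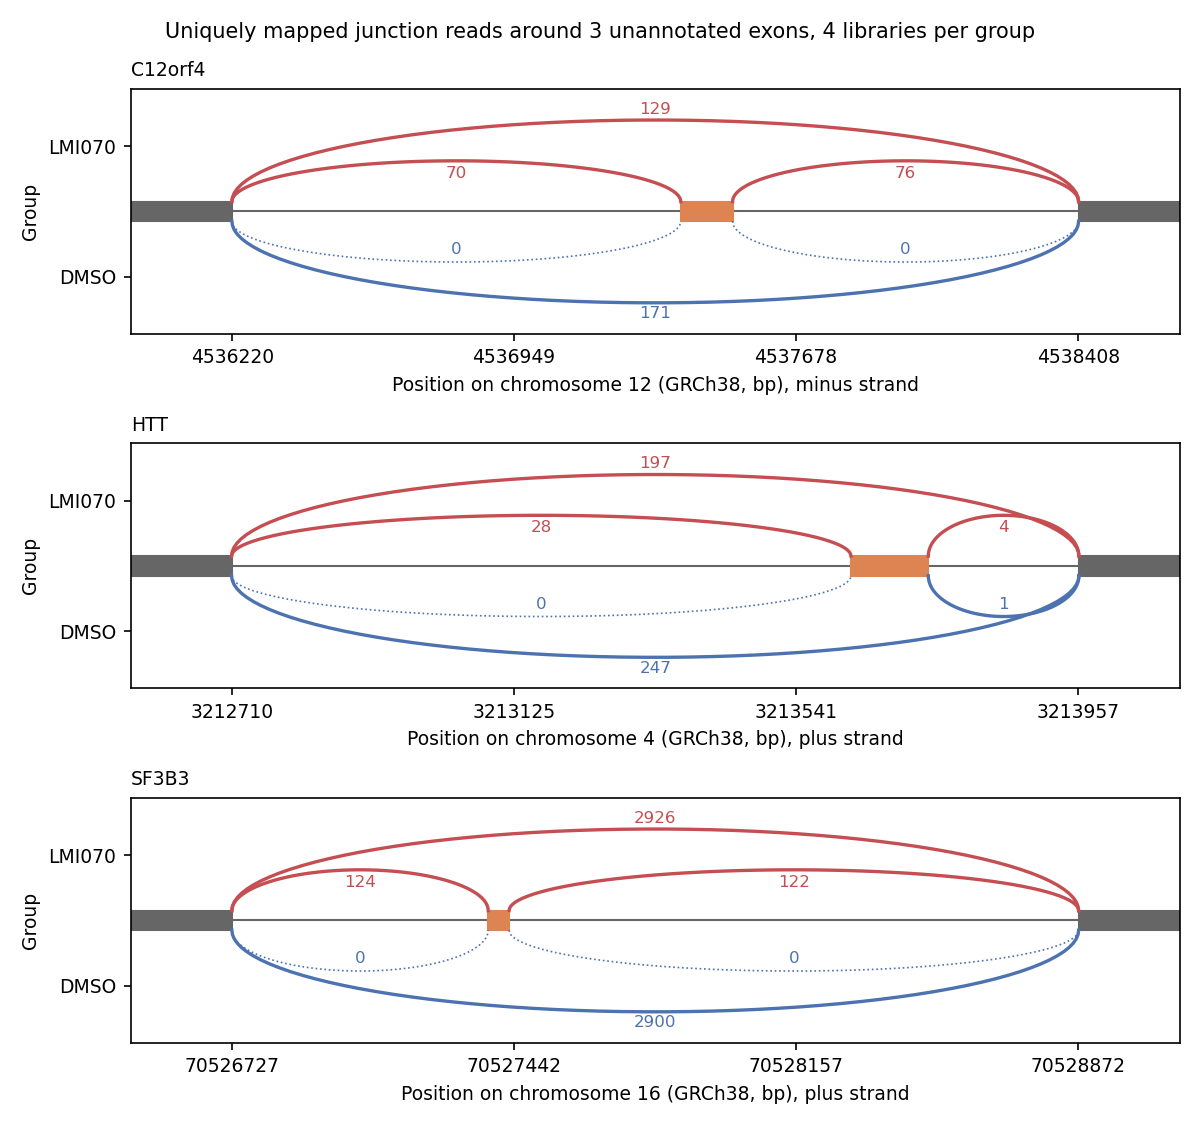
Uniquely mapped reads of the junctions around the unannotated exons (orange) of C12orf4, HTT and SF3B3, summed over the 4 libraries of each group, with LMI070 arcs above and DMSO arcs below the line and the number of reads at each arc. The horizontal axis is the position in bp on GRCh38, introns are to scale, the grey flanking exons are cropped, and dotted arcs had 0 reads. In C12orf4 the exon's junctions had 70 and 76 reads in LMI070 and 0 in DMSO.

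LMI070 is known from other work to act at 5′ splice sites whose exon ends in GA, so the last bases of the exons were compared. This comparison on annotated exons was chosen after the data were seen. Of the 15 annotated exons called higher, 13 (86.7%) ended in GA, against 325 of the 18767 tested and called in neither direction (1.73%). Fisher's exact test gave a two-sided p of 1.68e-21. The last 3 bases were AGA in 12 of the 15 (80%) and in 149 of the 18767 (0.794%), POMT2, STRN3, KDM6A, PDE7A and TRIM65 among the former. The exceptions were in FAAP20 (CAG) and the 90-nt exon of VPS29 (AAG); the 12-nt exon of VPS29 ended in AGA. Reference transcripts held the sequence of 3 of the 23 unannotated exons called higher, too few for a test. The ZNF37BP exon had the site AGAGTAAGA, while the called forms of SKP1, with 5 and 2 reads at their 5′ splice sites in LMI070, ended in TGA and CAT. The deepest SKP1 junction seen only in LMI070 (95 reads) left the end of a further form, from 134175284 to 134175385, which ended in AGA. That form rose by 0.780 points, under the minimum for a call. The skipping junction was chosen for each form separately, so the sizes do not rank the forms. Outside the called exons, PDXDC1 had AGAGTAAGA and BECN1 AGAGTAAGG, while forms of CYB5B ended in CCG, TAA and TAG. Of the 92 unannotated exons higher without a minimum change, 12 had sequence, and 7 of these ended in GA. A genome sequence was not used here.

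**Figure D4:**
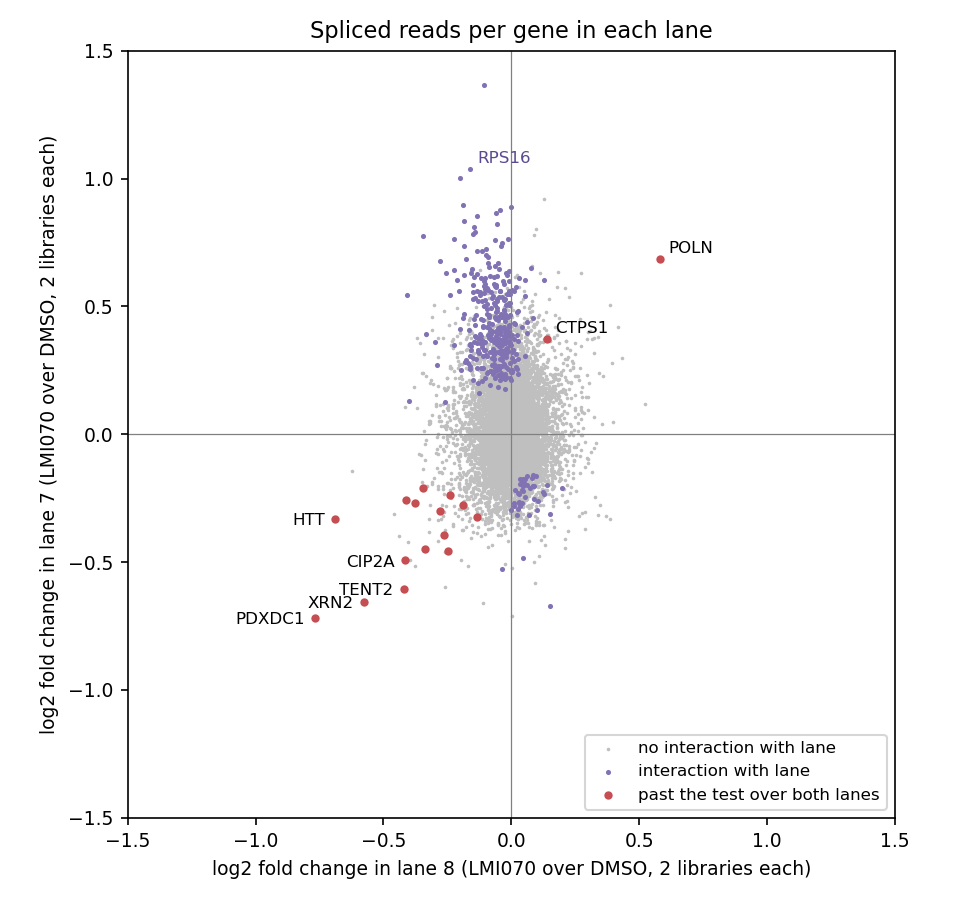
Log2 fold change of spliced reads per gene (LMI070 over DMSO) in lane 7 (vertical) against lane 8 (horizontal), each from 2 libraries per group, for the 10117 genes with a mean of at least 100 reads. Red points passed the test over both lanes, purple points had a different fold change in the lanes, and grey points are the others. PDXDC1 lies at -0.72 in lane 7 and -0.77 in lane 8, while RPS16 lies at 1.04 and -0.16.

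Junction usage, the share of a junction among all that use either of its splice sites, was compared to find changes that are not whole exons. In SKP1 an unannotated junction (chromosome 5, 134174515 to 134175283) went from 0% of usage, where 0 of 86 reads allow up to 3.49%, to 37.0% ± 6.24 (SD, n = 4). TCF12, a transcription factor gene, used an unannotated junction (chromosome 15, 57091892 to 57093490) at 3.26% ± 3 in DMSO and 33.4% ± 8.50 in LMI070, while the annotated junction to 57166401 went from 96.7% ± 3 to 61.8% ± 9.71. ARL15, a gene for an ARF-like GTPase, shifted from the junction starting at 54171929 on chromosome 5 (93.6% ± 3.42 to 68.6% ± 1.95) to that starting at 54307947 (1.74% ± 1.26 to 28.6% ± 2.47), both ending at 54310431. SREK1, a splicing regulator gene, raised a junction to 66164607 on chromosome 5 from 10.5% ± 1.79 to 26.0% ± 3.85, and its alternative to 66164782 went from 89.0% ± 1.55 to 72.8% ± 3.77. ATG2B, an autophagy gene, raised a junction on chromosome 14 (96317856 to 96318233) from 2.47% ± 0.885 to 16.3% ± 4.86. The junctions over the skipped exon of DLGAP4 (chromosome 20, 36497067 to 36499587) and HTT (chromosome 4, 3212710 to 3213957) went from 97.7% ± 3.56 to 78.9% ± 7.03 and from 96.9% ± 4.15 to 81.4% ± 0.511. Over 129495 junctions tested, edgeR called 51 higher, 26 of them unannotated, and 35 lower, of which 9 and 10 lay outside the called exons. The ATG2B call was lost without any single one of 6 libraries (adjusted p 0.567 without LMI070 replicate 14), without the low-count filter (0.934) and with multi-mapped reads (0.0529). In lane 8 alone the falling ARL15 junction (1.00) and the SREK1 junctions to 66164607 (0.249) and 66164782 (0.0648) did not pass. DLGAP4 passed in neither lane alone (0.622 and 0.519 in lanes 7 and 8), not without the low-count filter (0.123) and not without DMSO replicate 10 (0.135). The HTT junction passed in neither lane alone (1.00 and 0.512), not without the filter (0.506), and not without DMSO replicates 9 (0.0774), 10 (0.101) or 12 (0.441) or LMI070 replicate 14 (0.0677). With diffSpliceDGE the lower junctions of TCF12, ARL15, DLGAP4, SREK1 and HTT did not pass, and 15 were called lower.

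Junctions seen in every library of one group and in none of the other were counted as a further reading of drug-dependent exons. SF3B3, BECN1, GXYLT1, SKP1, C12orf4 and SSBP1 gave the deepest of those confined to LMI070; the SF3B3 junctions had 124 and 122 reads and the BECN1 junctions 97 and 63. Each of the 4 libraries of a group had to hold a read, so the minimum of 3 reads removed none here. With at least 3 reads, 408 unannotated junctions were seen only in LMI070 and 194 only in DMSO. Of the 35 splits of the libraries into 4 and 4, 7 gave as many on their larger side, so chance is not excluded for the 408. After all libraries were thinned to the smallest depth the counts were 346 and 220, and with at least 10 reads they were 90 and 8. Unannotated junctions took 0.892% ± 0.00291 of the junction reads in DMSO and 0.919% ± 0.0146 in LMI070 (SD, n = 4). The difference was 0.0264 points, 0.0366 in lane 7 and 0.0162 in lane 8, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allows, and 0.0429 after adjustment over 3 shares. AT-AC introns, which the minor spliceosome removes, took 0.106% of the reads in both groups (0.106% ± 0.00126 and 0.106% ± 0.000719; exact permutation p 0.486), and the difference had opposite signs in the lanes (-0.00188 in lane 7 and 0.000740 in lane 8). Multiply mapped reads took 2.50% ± 0.05 and 2.55% ± 0.00716 (exact permutation p 0.0286, adjusted 0.0429).

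Spliced reads per gene, the sum over the annotated junctions of a gene, were compared to find genes whose spliced RNA changed. PDXDC1 fell by 0.74 on the log2 scale (SE 0.04), from 271 ± 3.71 to 162 ± 6.15 CPM (scaled counts; SD, n = 4). XRN2, a nuclear exoribonuclease gene, fell by 0.62 (SE 0.04), from 596 ± 14.7 to 389 ± 8.88 CPM. TENT2 fell by 0.52 (SE 0.06), HTT fell by 0.51 (SE 0.06), and CIP2A, a gene for a phosphatase inhibitor, fell by 0.46 (SE 0.04). FBXO9 fell by 0.40 (SE 0.04), FHOD3 fell by 0.34 (SE 0.05) and LNPK fell by 0.33 (SE 0.05). SLC7A6, an amino acid transporter gene, fell by 0.32 (SE 0.06), the checkpoint kinase gene CHEK1 fell by 0.29 (SE 0.05) and L3MBTL2 fell by 0.28 (SE 0.05). POLN, a DNA polymerase gene, rose by 0.65 (SE 0.07), from 19.8 ± 1.28 to 31.1 ± 3.36 CPM, and CTPS1, a CTP synthase gene, rose by 0.26 (SE 0.04). HTT went from 275 ± 4.15 to 195 ± 31 CPM and fell by 0.33 in lane 7 and by 0.69 in lane 8 (edgeR adjusted p of the difference 0.00189).

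Over 13487 genes, edgeR with lane in the model had 3 genes higher and 15 lower at an adjusted p under 0.05, and 1392 at an unadjusted p under 0.05. The genes past the test and outside the rule for naming were DIAPH3, CEP170 and NAE1, which fell by 0.24, 0.23 and 0.23, and ZNF837, which rose by 1.81 (SE 0.25) on a mean of 30.6 reads per library. All 15 were lower and all 3 higher in both lanes. DESeq2 had 9 higher and 27 lower. The difference in gene levels between LMI070 and DMSO libraries depended on the lane. An interaction of treatment with lane passed for 385 genes at an edgeR adjusted p under 0.05. RPS16, a ribosomal protein gene named after its values were seen, had a log2 fold change of 1.04 in lane 7 and -0.16 in lane 8. The interaction does not tell a different response to the drug from lane 7 libraries that differ for other reasons. Lane 7 alone had 472 genes higher and 85 lower, and lane 8 alone 11 and 40. CTPS1 did not pass without the lane term (adjusted p 0.178), nor without DMSO replicate 11 (0.114), LMI070 replicate 13 (0.125) or LMI070 replicate 16 (0.0990). Without LMI070 replicate 14, 8 genes were lower, and FHOD3, SLC7A6, CHEK1 and L3MBTL2 were among those that did not pass (0.0508, 0.0682, 0.0508 and 0.0877). L3MBTL2 also did not pass without DMSO replicates 9 (0.0773), 10 (0.0700) or 11 (0.114) or LMI070 replicate 13 (0.0536), SLC7A6 without DMSO replicate 9 (0.0847), and CHEK1 without LMI070 replicate 13 (0.0501). In lane 7 alone FHOD3 (0.0707), SLC7A6 (0.0909) and L3MBTL2 (0.125) did not pass.

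Among genes known as targets from other work, PDXDC1 and HTT fell and no other of the 11 measured passed over all genes. Adjusted over the list alone, SLC25A17 (-0.13, SE 0.05) was also lower and SMN2 (0.37, SE 0.09) higher. SMN2 had 13.8 ± 1.59 CPM in DMSO and 17.9 ± 0.831 in LMI070 with an adjusted p of 0.147 over all genes (0.0457 with DESeq2). Its log2 fold change was -0.02 with multiply mapped reads added. Most uniquely mapped reads of SMN2 crossed the junctions into and out of exon 7. Summed over libraries these had 591 and 463 reads in DMSO and 815 and 619 in LMI070, beside a gene mean of 375 reads per library. The rise thus largely counts reads at exon 7 and cannot be read as a change of the whole SMN2 RNA. SMN1 was at -0.03 (SE 0.07). FOXM1 was at 0.31 in lane 7 and -0.03 in lane 8 (adjusted p of the difference 0.0200). STRN3 (0.10), GGCT (0.04), MADD (0.08), APLP2 (0.05), POMT2 (0.02) and VPS29 (-0.06) did not pass. This list's median was 0.04 while its camera test pointed down (adjusted p 0.894); with fry the adjusted p was 0.0187. Genes named by the study on these samples, 3 measured, had 0 past the test: SF3B3 at 0.00, BECN1 at 0.05 and C12orf4 at -0.09 (adjusted p of the list 0.894). The list was chosen on these libraries and is not independent evidence; PDXDC2P was not measured at gene level.

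Of the gene lists fixed beforehand, cholesterol synthesis and uptake fell as a set: 15 of 20 measured genes were lower, with a median log2 fold change of -0.07 (camera adjusted p 0.00752, but adjusted p = 0.250 with an estimated correlation). No member passed over all genes with edgeR or DESeq2, 7 were lower and 0 higher at an unadjusted p under 0.05, and INSIG1 (-0.16, SE 0.04) passed adjusted over the list alone. CYP51A1, a gene of the same pathway, was at -0.27 (SE 0.09). The medians were -0.09 in lane 7 and -0.05 in lane 8, and the set did not pass in lane 7 alone (adjusted p 0.139). With fry its adjusted p was 0.0209. Noncoding host genes that are sensitive to nonsense-mediated decay were lower in 13 of 14 measured, with a median of -0.07 (camera adjusted p 0.0409, adjusted p = 0.938 with an estimated correlation and 0.553 with fry); SNHG6 was at -0.15 (SE 0.07) and GAS5 at -0.12 (SE 0.05). Their median was -0.16 in lane 7 and 0.02 in lane 8, and the set did not pass without DMSO replicates 11 (0.0805) or 12 (0.593) or LMI070 replicates 13 (0.160) or 16 (0.503). No list passed with an estimated correlation.

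The other lists did not pass. SMN complex genes had a median of -0.01 (adjusted p 0.894), and SMN2 alone passed over the list, largely on reads at exon 7. SF3a, SF3b and U2 snRNP protein genes were at 0.00 (0.862), with SF3B4 (0.26, SE 0.08) and SF3A1 (0.21, SE 0.07) higher when adjusted over the list alone. U1 snRNP and Sm protein genes were at 0.00 (0.894), SR proteins and poison-exon regulators at 0.00 (0.894) and decay factors at 0.02 (0.425). Oxidative phosphorylation genes were at -0.04 (0.0558), with a median of -0.09 in lane 7 and 0.00 in lane 8, and cytosolic ribosomal protein genes at -0.02 (0.862). Medians were -0.01 for p53 targets (0.894), 0.01 for the integrated stress and unfolded protein responses (0.894), 0.02 for heat shock proteins (0.862), -0.01 for interferon response (0.894) and 0.01 for autophagy (0.894). They were -0.02 for G2 and M phase genes (0.862), 0.01 for DNA replication and S phase genes (0.894) and -0.01 for glycolysis (0.894). HEK293 identity genes were at 0.02 (0.862). Of markers of other cells, 0 of the 10 for blood and 0 of the 8 for hepatocytes were measured. The 4 measured for keratinising or cervical epithelium were at 0.03 (0.894) and the 3 for fibroblasts at 0.09 (0.862), with COL1A1 (0.30, SE 0.09; 0.50 in lane 7 and 0.07 in lane 8) past the test over the list alone. The camera direction was opposite to the median for the SMN complex, both target lists, U1 snRNP, glycolysis and autophagy.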

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

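The tests on drug exposure in lane 7 and on SMN exon 7 with multiply mapped reads were chosen after the result was seen.

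SMN exon 7 is the exon whose inclusion LMI070 was developed to raise. Its skipping reads map to both SMN1 and SMN2 and lie in the count of multiply mapped reads, which the main measurement does not use. Here those skipping reads were set against the uniquely mapped reads of the upstream junction into exon 7 alone, summed over both genes. The downstream junction was left out, unlike in the inclusion used elsewhere. Joint inclusion in both genes (chromosome 5, 70076521 to 70076574 and 70951941 to 70951994) was 80.9% ± 1.81 in DMSO and 90.8% ± 0.319 in LMI070 (SD, n = 4). It was 11.3 points higher in lane 7 and 8.49 in lane 8. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 can give. The skipping reads went from 99.8 ± 10.5 to 50 ± 14.3 per library. SMN2 took 35% ± 3.60 of the uniquely mapped reads into exon 7 in DMSO and 41.7% ± 2.95 in LMI070. The reads do not say from which gene the skipping came.

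The log2 fold change of spliced reads differed between the lanes for CTPS1 (0.37 in lane 7 and 0.14 in lane 8, edgeR adjusted p of the difference 0.0371), HTT (-0.33 and -0.69, 0.00189) and FOXM1 (0.31 and -0.03, 0.0200). Of the 385 genes with such a difference, which include these and RPS16 (1.04 and -0.16), 380 had the larger change in lane 7. The number depends on single lane 7 libraries: it was 231 without LMI070 replicate 13 (207 of the 385 among them), 235 without LMI070 replicate 16 (223), 553 without DMSO replicate 12 (347) and 1597 without DMSO replicate 11 (384). Lower exposure to the drug in lane 7 is argued against by the exons alone. Their rise was smaller in lane 7 for 68 of 145 rising exons (exact binomial p 0.507, two-sided). However, the median rise was 4.15 points in lane 7 and 4.84 in lane 8, and 12 and 24 unannotated exons were called in them. The larger gene changes in lane 7 cannot decide on exposure, since the explanations left open below could give them at any exposure. Single libraries that stand apart stay open: without DMSO replicate 12 and LMI070 replicate 16 the number was 900 and 371 of the 385 were among them, but lane 7 then had 1 library per group, assumed to vary like those of lane 8. A GC bias of the lane 7 libraries is a candidate explanation that could not be excluded: the genes concerned had the higher transcript GC in a share of 0.641 of pairs matched for reads (random sets gave 0.474 to 0.526). Cultures, libraries or runs that differ between the lanes cannot be told apart from it, and no biological explanation was tested.

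Single libraries stood apart from the other 3 of their group in 10 of 136 groups tested, and DMSO replicate 12 held 4 of the 10. The limit used gives about 5% by chance for continuous values, but 1 read beside counts of 0 always passes it. Both CACNA2D1 exons also rest on the same read. The 10 and the 4 therefore cannot be weighed against chance. In DMSO, DYRK1A had 4% in replicate 9 (95% Wilson interval 0.419 to 29.2), TET1 2.44% in replicate 9 (0.255 to 19.6), FAM3A 3.03% in replicate 12 (0.317 to 23.5), both CACNA2D1 exons 0.606% in replicate 12 (0.0633 to 5.54) and HTT 0.840% in replicate 11 (0.0878 to 7.56). Each of these came from 1 read where the other DMSO libraries had 0. LINC02210 had 1.29% in DMSO replicate 11 (0.355 to 4.58), and the others had 2.84% to 3.01%. WDR27 had 23.8% in LMI070 replicate 13 (15 to 35.6), and the others 19.3% to 20%. The 90-nt exon of VPS29 had 76.1% in LMI070 replicate 16 (67.8 to 82.8), and the others 67.9% to 69.1%. CIP2A had 217 CPM in DMSO replicate 12 and 191 to 195 in the others.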

How the results depend on the processing

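Balanced junctions, each lane alone and leaving out both libraries that stand apart were chosen after the data were seen. The cause of the changes below was not tested.

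Unannotated exons higher in LMI070 numbered 23. They numbered 92 without a minimum change, 11 at 20 points, 14 with balanced junctions, 9 with at least 50 reads per library, 12 in lane 7 alone and 21 to 23 with 1 library left out. Those lower numbered 0, and 3 without a minimum change. Annotated exons higher numbered 15, with 40 without a minimum change, 9 with DESeq2 and 11 to 15 with 1 library left out. The exon lower (RAB3IP) became 4 without a minimum change. It became 0 at 20 points, without the low-count filter, with DESeq2, in lane 7 alone and in lane 8 alone. With 1 library left out it was 0 to 1, with 0 without DMSO replicate 11 and without LMI070 replicate 16.

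Junctions with higher usage numbered 51, with 115 without a minimum change, 31 with at least 50 reads, 29 in lane 7 alone, 26 in lane 8 alone and 42 to 48 with 1 library left out. Those with lower usage numbered 35, with 71, 22 and 22 in the first and the lane settings, 15 with diffSpliceDGE and 30 to 34 with 1 library left out. Unannotated junctions seen only in LMI070 numbered 408, with 90 at a minimum of 10 reads, 4524 in lane 7 alone, 2642 in lane 8 alone, 1712 without both libraries that stand apart and 630 to 1165 with 1 left out. Those seen only in DMSO numbered 194, with 8, 2261, 2855, 976 and 333 to 658 in the same settings. More were seen only in DMSO than only in LMI070 in lane 8 alone, and also without DMSO replicate 9 (641 and 630). Fewer libraries make it easier to be absent from a group.

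Genes higher numbered 3, with 204 without the low-count filter, 472 in lane 7 alone, 11 in lane 8 alone, 9 with DESeq2 and 2 to 6 with 1 library left out (5 without DMSO replicate 10, 6 without LMI070 replicate 15). Genes lower numbered 15, with 61, 85, 40 and 27 in the same settings and 8 to 15 with 1 library left out (8 without LMI070 replicate 14). Lists past the threshold numbered 2, with 0 with an estimated correlation, 1 without both libraries that stand apart and 1 to 3 with 1 library left out. That number was 1 without DMSO replicate 11 or 12 or LMI070 replicate 13 or 16. The noncoding host genes sensitive to decay reversed in lane 8 alone, with a median of 0.025 (adjusted p 0.751).

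The share of unannotated reads rose by 0.0264 points, with 0.0366 in lane 7, 0.0162 in lane 8 and 0.0210 to 0.0308 with 1 library left out (0.0210 without LMI070 replicate 16). As a share of junction number it rose by 1.1 points (exact permutation, adjusted p 0.857). The share of AT-AC reads was -0.00188 in lane 7 and reversed to 0.000741 in lane 8, and -0.000988 to -0.000147 with 1 library left out. The share of multiply mapped reads by junction number rose by 0.202 points (exact permutation, adjusted p 0.857), and by 0.0348 to 0.0691 points of reads with 1 library left out.

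Of the alternatives for single named exons, 252 left the adjusted p under 0.05 and 38 did not, whatever the size of the change. With 1 library left out these were 291 and 13. Settings in which an exon was not tested were left out, and target exons with changes under 10 points were included. For named junctions they were 46 and 16, and 69 and 11. For named genes 255 were as before, 5 weaker, 4 stronger and 6 moved; with 1 library left out 203 were as before and 13 weaker.

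Depth limits exons with few reads: inclusion below a few percent rests on single reads in a library, and small changes in weakly expressed genes are out of reach. The planned test of the 5′ splice site of unannotated exons and its alternatives were not run, since reference transcripts held the sequence of 13% of the called exons.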

Other observations

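The tests of whether an unannotated exon lowers the spliced RNA of its gene and of unannotated junctions with at least 10 reads were chosen after the result was seen, as was the comparison of junctions outside the host intron.

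Several genes whose spliced reads fell held an unannotated exon that rose by less than 10 points. XRN2 included a 54-nt exon in intron 16 (chromosome 20, 21345834 to 21345887) at 0.378% in DMSO and 3.68% in LMI070. CIP2A included a 181-nt exon (chromosome 3, 108565898 to 108566078) at 1.61% and 6.29%, and LNPK included a 219-nt exon (chromosome 2, 175970199 to 175970417) at 0.421% and 4.23%. DIAPH3 included a 48-nt exon (chromosome 13, 59974085 to 59974132) at 0% and 2.67%. They and PDXDC1 and HTT, and TENT2 and FHOD3 with exons that rose by more, were among 9 falling genes with a rising unannotated exon. The falling genes without a rising unannotated exon were FBXO9, SLC7A6, CHEK1, L3MBTL2, CEP170 and NAE1, and SLC7A6 held a rising annotated exon.

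Of the 13 falling genes with a tested unannotated exon, 9 (69.2%) held one that rose, against 56 of the other genes (1.6%) among 3509 (Fisher's exact test, two-sided, p 9.80e-14). Easier calls in deeply covered genes are argued against, since none of 100000 draws of genes matched for reads held as many (at most 5; p 1e-05, the smallest that the draws can give), and so are reads that moved to unannotated junctions of the host intron, since the median log2 difference was -0.45 without the junctions of that intron and -0.46 with them. Whether the exon length mattered could not be told: genes with exons whose length is not a multiple of 3 did not differ from the others by a test (permutation p 0.845, two-sided), and of the 9 genes 5 had a multiple of 3 and 4 did not. Over the 63 coding genes with a rising unannotated exon the median log2 fold change was -0.06. The size of the rise and the log2 fold change had a Spearman correlation of 0.136 (permutation p 0.287, two-sided). That value does not decide the question, since inclusion is measured on the RNA that remains. Loss of included RNA would lower the measured rise as well. Inclusion of the exon may still lower the spliced RNA of its gene, as a hypothesis found and tested on the same libraries; inclusion of 3.68% in XRN2 beside a fall of 0.62 would need most of the included RNA to be lost before it is counted, and decay was not measured.

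Other splits of the 8 libraries into 4 and 4 were refitted. Chance is argued against for the 23 unannotated exons (highest other split 0, 1 of 35 splits as large) and the 16 annotated exons (0, 1 of 35). It is also argued against for the 86 junctions with changed usage (26, 1 of 21). A share of 1 of 35, or 1 of 21, is the smallest that these splits can give. The 90 unannotated junctions with at least 10 reads seen only in LMI070 also stood alone (35, 1 of 35). Their minimum of 10 reads was chosen after the result was seen, so that count does not decide the question. Chance cannot be excluded for the 408 junctions with at least 3 reads (472, 7 of 35) and the 2 gene lists (3, 7 of 35). For the 15 falling genes 3 of 35 splits were as large (highest other 67), so this count of splits does not exclude chance, but both other splits follow the lanes and every split apart from these gave 0. The split of lane 7 against lane 8, fitted without a lane term, gave the 67 genes, several times the real count, which points to a structure of the samples by lane. The split that sets DMSO replicates 9 and 10 with LMI070 replicates 13 and 16 against the rest, which is the difference of the treatment effect between the lanes, gave 16. Within lanes, 85 genes fell in lane 7 and 40 in lane 8, and all 15 were lower in both.

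PDXDC2P and PDXDC1 are paralogs, as are copies of GTF2H2, and reads shared between copies are left out of uniquely mapped counts, so their inclusion refers to the reads that can be placed. With multiply mapped reads added, 26 unannotated exons were called higher.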
